A study of Rattus norvegicus with 96 samples.

How the data were processed

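The series holds 96 arrays of rat brain tissue. The tissue was the central nucleus of the amygdala, a part of the forebrain engaged in fear, stress and drug-related behaviour. The animals came from 5 pairs of rat lines bred for high or low alcohol preference. In each pair the preferring line is named first here: HAD1 and LAD1, HAD2 and LAD2, P and NP, AA and ANA, and sP and sNP. The groups held 9 HAD1, 10 LAD1, 10 HAD2, 10 LAD2, 10 P, 10 NP, 10 AA, 10 ANA, 8 sP and 9 sNP arrays. The labels used here give no sex, age, alcohol exposure or hybridisation date. Group and replicate number were taken from the sample titles. The sample titled LAD1 36 is called LAD1 in its title and preference label and HAD1 in its source name; it was kept as LAD1, and both other treatments were planned as alternatives.

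Per the labels, biotin-labelled cRNA was prepared from 25 ng of total RNA by the 2-cycle protocol of Affymetrix and hybridised to rat arrays. The deposited values are on a log2 scale and were made by the authors with RMA, a method that corrects background, normalizes arrays and summarises the probes of a probe set. The version of RMA and whether the 5 line pairs were normalized together are not given in the sources used here. The distributions of values grouped by line pair, and every comparison was therefore made within line pairs. No detection calls were used, so a probe set near background was not told apart from one with low expression, and the number of arrays limits the precision. The table had 0 value columns that belonged to no sample.

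The 57 AFFX control probe sets were left out, which left 31042 probe sets. In the platform annotation, 20826 of these carried 1 gene symbol, 436 carried several and 9780 were not listed and stay unnamed. Symbols were checked through the Entrez identifier against a RefSeq table of the GRCr8 assembly, where 20758 matched and 0 symbols changed. That table was used only for names, chromosomes and the order of neighbouring genes, because the build behind the array annotation is not given in the sources used here. A gene was represented by its 1-symbol probe set with the highest mean over all 96 arrays, which gave 14217 genes. A probe set measures the sequence its probes match, and a sequence difference between lines under a probe can shift its value without a change in expression.

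Tests used limma 3.58.1 in R 4.3.3. Each line pair was fitted on its own arrays with moderated variances and an intensity trend; tests had no preset direction, with Benjamini-Hochberg adjusted p under 0.05 over all 31042 probe sets. A second fit of all 10 groups gave the mean of the 5 differences with equal weight per pair, and an F test of whether the 5 differences vary. A further fit took the 5 differences of group means as the replicates. Differences are given as preferring minus non-preferring line, in log2 units with standard errors; levels are given as mean ± SD. Correlations of differences between pairs run across probe sets, which are not independent replicates, and were set against 100 permutations of the labels within pairs. The 24 gene lists were tested with limma's camera at a preset correlation of 0.01 on 1 probe set per gene, adjusted over the lists within a contrast, and with an estimated correlation and fry as alternatives. Of the 447 genes in these lists, 402 were measured through the annotation and 45 were not analysed here. P-values measure the spread between arrays of a line; animals of a line share descent, so the line pair is the unit in which selection was repeated.

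Tests, lists, the rule for named genes and most alternatives were chosen before the data were examined; the alternatives on doubted or nearly identical arrays came afterwards. The rule takes, per line pair, the 6 genes with the largest difference in each direction past the test, 10 in each direction for the mean over pairs, the 5 smallest p for variation among pairs, at most 10 genes changed the same way in 4 or 5 pairs, and at most 2 members per direction from each list. Npy, Grm2, Crh and Gabra2 are always given; 2 further genes fixed for this purpose are not analysed here. Genes without an informative symbol were skipped, which concerned 1 gene for HAD2 and LAD2 and 2 genes for the mean. In the 3 pairs without a call, the 4 genes with the smallest p are also given; these were chosen after their values were seen.

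The place of each array between both lines of its pair was scored without that array. The 100 probe sets that best separated the lines by median and median absolute deviation, with 0.1 added to the deviation, were picked from the other arrays. The score is the array's median position on these, with +1 at the median of the preferring line and -1 at that of the other line. Odd-numbered and even-numbered chromosomes were scored separately. An array on the other line's side of the midpoint in both scores is called doubted, and counts are also given without the 15 doubted arrays. This rule was written after the data were seen: an earlier version of the scores, the present scores and counts without a list of arrays picked by eye had been looked at first. That list lacked ANA 18 and held sNP 2 in addition. Leaving out arrays that resemble the other line raises counts by construction. Probe sets on odd chromosomes were also tested without the arrays out of place on even chromosomes, and the reverse. Nearly the same arrays were left out either way, so a factor that acts on a whole array can raise these crossed counts too. No crossed counts were made with shuffled labels. No array was moved to another group on the basis of its values, and the counts with the labels as deposited are the main ones.

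Alternatives covered the brighter 50% of probe sets, a fold threshold of 1.2, fits without the intensity trend, quantile normalization, array weights, the ratio of 3' to 5' control probe sets as a covariate, all 10 groups in 1 fit, 1 probe set per gene, single arrays or line pairs left out, the shared replicate number as a block, an additive model of pair and preference, and other probe sets of a named gene. The code was tested on simulated data with the real means and spreads and 200 changed probe sets. For HAD2 and LAD2 it recovered 59.7% of changes of 1.2-fold, 94.0% of 1.5-fold and 100% of 2-fold over 31042 probe sets, with 13 false calls. For AA and ANA it recovered 26.9%, 77.6% and 93.9%, with 5 false calls. The simulation drew every array from its labelled line, so these shares need not hold for pairs with doubted arrays. The F test recovered 98.5% of 2-fold changes in 1 pair, with 67 false calls, more than the threshold names; the cause was not tested.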

Results

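RNA from the central amygdala was measured on 96 arrays from 10 rat lines, which form 5 pairs bred for high or low alcohol preference. The question the design poses is which genes differ between the lines of a pair and whether such differences recur over pairs. Median log2 values of the arrays lay between 7.77 and 8.02. The ratio of 3' to 5' control probe sets, a sign of RNA quality, differed between line pairs: the log2 ratio of 3' to 5' probe sets of GAPDH was 3.43 ± 0.58 (SD, n = 10) in HAD2 and 3.84 ± 0.66 (n = 9) in HAD1, against 0.20 ± 0.07 (n = 10) in P and 0.30 ± 0.03 (n = 8) in sP. Levels were therefore compared only within pairs.

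The arrays of 4 pairs did not all resemble the line on their label. HAD2 and LAD2 separated fully, with 0 of 20 arrays on the other line's side. HAD1 28 lay at -1.04 on odd and -1.02 on even chromosomes, where +1 is the median of HAD1 and -1 that of LAD1, and LAD1 37 lay at 0.76 and 0.83. Among 20 P and NP arrays, P 1, P 9, NP 1 and NP 9 lay on the other side. The same held for AA 15, AA 17, AA 19, ANA 16 and ANA 18 among 20 AA and ANA arrays, and for sP 2, sP 9, sNP 8 and sNP 9 among 17 sP and sNP arrays. NP 1 at 0.49 and 0.22 and ANA 18 at 0.13 and 0.02 were close to the midpoint. With shuffled labels the lowest number of such arrays in 20 permutations was 4 for HAD1 and LAD1 (2 observed), 4 for HAD2 and LAD2 (0 observed), 3 for P and NP (4 observed), 5 for AA and ANA (5 observed) and 3 for sP and sNP (4 observed). The medians of these permutations were 9.5, 10, 9.5, 9.5 and 7 in that order, above the observed number in every pair. LAD1 36, whose labels contradict each other, lay on the LAD1 side at -0.73 and -0.95. In addition, sP 2 and sNP 2 were nearly the same: their values differed with an SD of 0.09 log2 units, against 0.16 for the next closest arrays of any pair. The 15 arrays on the other side in both scores are called doubted, and groups are as labelled throughout. Values without the doubted arrays rest on a choice made after the data were seen, and leaving out arrays that resemble the other line raises such differences by construction.

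**Figure D1:**
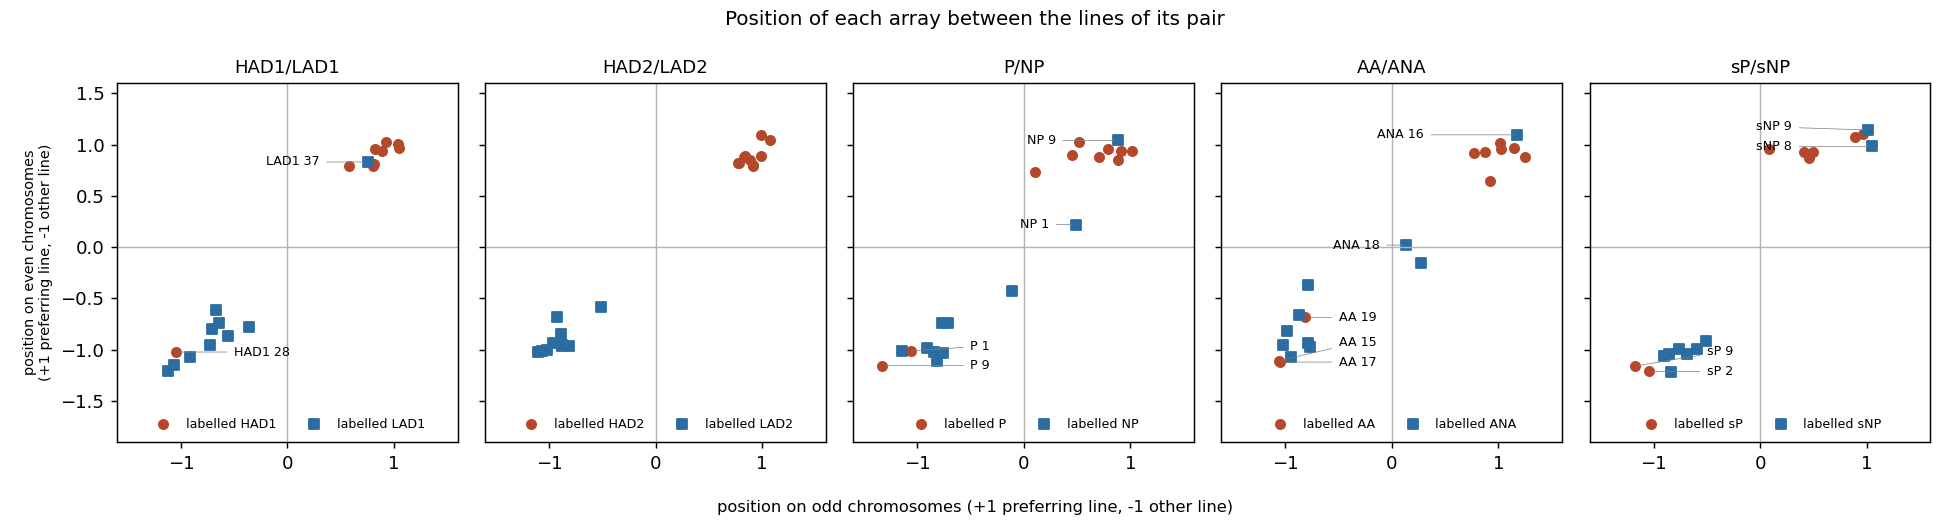
Position of each array between the lines of its pair, on odd-numbered (horizontal) and even-numbered (vertical) chromosomes, scored without that array; +1 is the median of the preferring line and -1 that of the other line. Circles are arrays labelled with the preferring line and squares arrays labelled with the other; the 15 named arrays lie on the other line's side in both scores, and none of these belongs to HAD2 or LAD2.

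HAD2 rats, bred for high preference, differed from LAD2 rats in more probe sets than any other pair. Among genes with an informative symbol, the largest reduction was in the brightest probe set of Sgcb, which encodes a sarcoglycan of the cell membrane: its level was 7.56 ± 0.24 in HAD2 and 10.95 ± 0.45 in LAD2 (SD, n = 10 each), 10.5-fold lower (limma adjusted p = 1.62e-13). Its 2 other probe sets were in the opposite direction, at 0.59, which passed (adjusted p = 0.0085), and at 0.31, which did not (adjusted p = 0.0741). Grm5, a metabotropic glutamate receptor, was 4.46-fold lower, Pnlip, a pancreatic-type lipase, 4.32-fold lower, Siglec5, a sialic acid-binding receptor of myeloid cells, 4.20-fold lower, Elavl1, an RNA-binding protein, 3.90-fold lower, and Slc3a1, a subunit of an amino acid transporter, 3.19-fold lower. The largest increase was in RT1-T24-4, an MHC class I gene, 5.01-fold higher, followed by Kif15, a mitotic kinesin, at 4.69-fold, Fcrl2, an Fc receptor-like gene, at 4.56-fold, Tstd1 at 2.39-fold, Gpatch11 at 2.35-fold and RT1-S3, another MHC class I gene, at 2.28-fold. For each of these 12 genes every HAD2 array lay on the named side of the LAD2 mean, and every LAD2 array on the other side of the HAD2 mean. In all, 1271 of 31042 probe sets passed the test, 677 higher and 594 lower in HAD2; with 1 probe set per gene 526 passed, and in the brighter 50% 831.

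Some transmitter and metabolic genes were among the changed genes of HAD2 rats, few in each list. Over all 14217 genes, 305 were higher and 228 lower past the test. Among the lists, 0 of 19 GABA, 0 of 25 neuropeptide, 0 of 27 neuropeptide receptor and 0 of 21 ion channel genes passed. The same held for 0 of 32 respiratory chain and 0 of 21 alcohol preference candidate genes. Lists this small would hold few called genes at the share over all genes, so counts of 0 or 1 set no list apart. Aldh1a1, an aldehyde dehydrogenase that makes retinoic acid, was 2.59-fold lower (SE 0.15 on the log2 scale), the 1 member past the test among 18 measured genes of alcohol and aldehyde metabolism. Ddc, the decarboxylase that makes dopamine and serotonin, fell by 0.46 (SE 0.07), and 5 of 30 monoamine genes had positive differences. Of 30 glutamate genes, Grin3a, an NMDA receptor subunit, rose by 0.91 (SE 0.17) and Grm5 fell. Chrna4, a nicotinic receptor subunit, fell by 0.40 (SE 0.08), Gsta4, a glutathione transferase, by 0.34 (SE 0.07). Adcy9, an adenylyl cyclase, rose by 0.63 (SE 0.09), Mt2A, a metallothionein in the glucocorticoid list, by 0.40 (SE 0.09), and Jun, an immediate early gene, by 0.32 (SE 0.09). Adjusted p for these 9 genes ranged up to 0.0419. Counts adjusted over the list alone were also 1 lower for monoamine, acetylcholine and alcohol metabolism genes, and 1 higher and 1 lower for glutamate genes. Camera called the monoamine list lower (adjusted p = 0.0309); with an estimated correlation adjusted p = 0.650.

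Cell type markers of HAD2 rats moved in both directions. P2ry12, a microglial purine receptor, rose by 0.64 (SE 0.08) while Cx3cr1, a microglial chemokine receptor, fell by 0.30 (SE 0.06). Among 12 vascular markers Abcb1a rose by 0.66 and Rgs5 by 0.42, and Tek fell by 0.28. Gjb6, an astrocyte connexin, rose by 0.28. In the MHC list of 16 genes, RT1-S3 rose and RT1-A3 fell by 0.33. Of the markers of central amygdala neurons 0 of 13 passed the test, as did 0 of 12 striatal, 0 of 15 oligodendrocyte, 0 of 10 choroid plexus and 0 of 9 basolateral or cortical markers. Of 2 other probe sets of Elavl1, 1 passed in the direction of the first at -0.57 (adjusted p = 2.49e-05) and 1 gave 0.12 (adjusted p = 0.4016). Other probe sets passed in the same direction for Grm5 at -0.40, Ddc at -0.45, P2ry12 at 0.55 and, with 3 of them from 0.58 to 1.05, RT1-S3. Those of Gpatch11, Jun, Abcb1a and RT1-A3 had the same sign and did not pass.

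**Figure D2:**
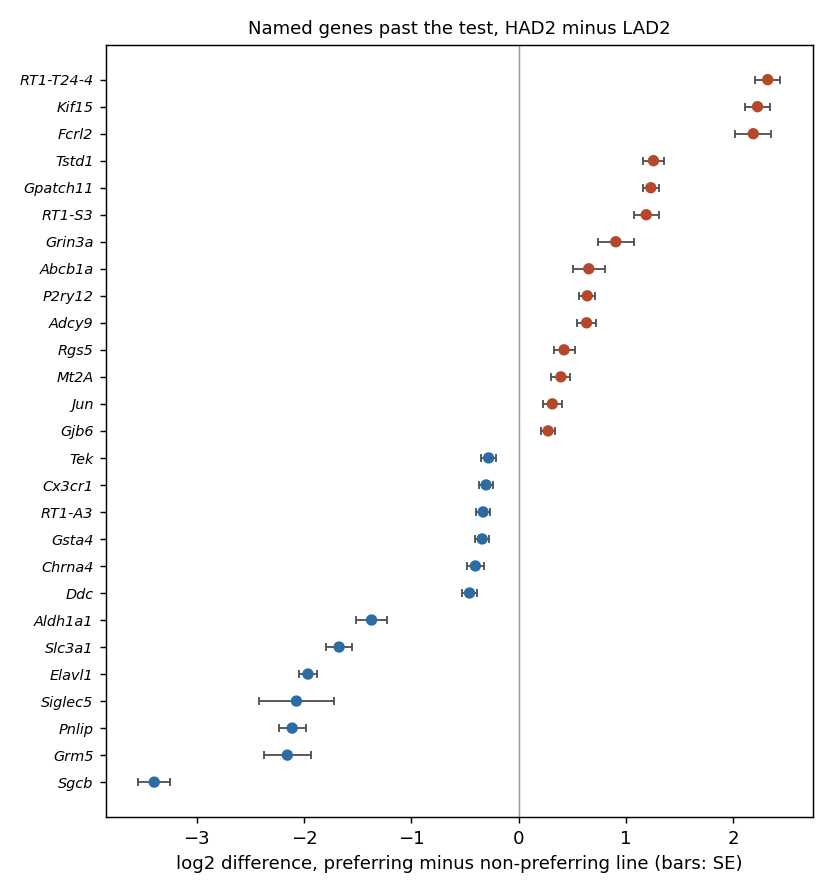
Log2 difference (horizontal axis, HAD2 minus LAD2) of the named genes past the test, 10 arrays per line; points are differences and bars standard errors. Sgcb fell by 3.40 and RT1-T24-4 was 2.32 higher, the ends of the range shown.

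HAD1 rats also differed from LAD1 rats. Amy1, a starch-digesting amylase, was at 8.69 ± 1.44 in HAD1 (SD, n = 9) and 5.49 ± 1.276 in LAD1 (n = 10), 9.24-fold higher (limma adjusted p = 0.0051), with 8 of 9 HAD1 and 9 of 10 LAD1 arrays in this direction. Cyp2j10, a cytochrome P450, was 4.19-fold higher, Kif15 3.41-fold, Nrg1, a growth factor of the epidermal growth factor family, 2.93-fold, and Elavl1 and Klhl42 were higher by 1.11 and 1.07 on the log2 scale. Mis18a, a centromere protein, was 8.48-fold lower, Nat8f3, an acetyltransferase-related gene, 2.72-fold, Grifin, a galectin-related gene, 2.25-fold, Grm5 2.06-fold, Tom1l3 2.05-fold and Nek1, a protein kinase, 1.94-fold. The test called 299 probe sets, 148 higher and 151 lower in HAD1. Without the doubted arrays HAD1 28 and LAD1 37 it called 796, 384 higher and 412 lower, and the log2 difference of Amy1 went from 3.21 to 4.06, that of Cyp2j10 from 2.07 to 2.701 and that of Mis18a from -3.08 to -3.88. With arrays chosen on 1 set of chromosomes and probe sets tested on the other, 388 of 20136 passed, against 114 as labelled. Array weights gave 700, all 10 groups in 1 fit 785, the brighter 50% 182 and 1 probe set per gene 78.

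Over all 14217 genes, 31 were higher and 66 lower past the test in HAD1 rats. Among the lists, Gabra3, a GABA receptor subunit, rose by 0.27 (SE 0.06), the 1 member past the test among 19 GABA genes. Gsta4 fell by 0.90 (SE 0.15) among 31 glutathione and antioxidant genes and Htr5b, a serotonin receptor, by 0.33 (SE 0.08) among 30 monoamine genes. Microglial markers were lower: 0 of 13 had positive differences, with C1qc falling by 0.48 (SE 0.11) and Cx3cr1 by 0.40 (SE 0.09), 2 past the test over all probe sets and 7 adjusted over the list alone. Positive differences were also few among astrocyte (1 of 11), oligodendrocyte (3 of 15) and vascular markers (2 of 12), none of these lists called by camera, against 8 of 13 for central amygdala, 6 of 9 for basolateral and cortical and 5 of 12 for striatal neuron markers. Camera called the microglial list (adjusted p = 1.32e-07) and the respiratory chain list (adjusted p = 0.000814, 3 of 32 positive, 0 members past the test); with an estimated correlation adjusted p = 0.414 and adjusted p = 0.689, and fry gave adjusted p = 0.0424 for microglial markers. Abcb1a fell by 0.67 and Igf2 by 0.45, and 0 of 13 central amygdala and 0 of 12 striatal markers passed. Other probe sets differed in sign for Grm5, at 0.05, Elavl1, at -0.11, Nrg1, at -0.01, and Igf2, at 0.04 to 0.08. None of the other probe sets of named genes passed in HAD1; those with the sign of the first were at 0.25 for Elavl1, 0.03 to 0.30 for Nrg1, 0.14 for Klhl42 and -0.22 for Abcb1a. Counting LAD1 36 as HAD1, as its source name has it, left 4 probe sets, and none of the 19 named genes past the test passed any longer. Without LAD1 36, the calls of Elavl1, Gabra3, Nat8f3, Htr5b, C1qc, Cx3cr1, Abcb1a and Igf2 were lost. Single arrays moved the count of 299 by over 1.5 times: it was 157 without HAD1 21, 159 without HAD1 23, 177 without HAD1 24, 192 without HAD1 25, 600 without HAD1 28, 175 without HAD1 29, 192 without LAD1 32, 177 without LAD1 33, 166 without LAD1 34, 191 without LAD1 35, 180 without LAD1 36 and 477 without LAD1 37.

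**Figure D3:**
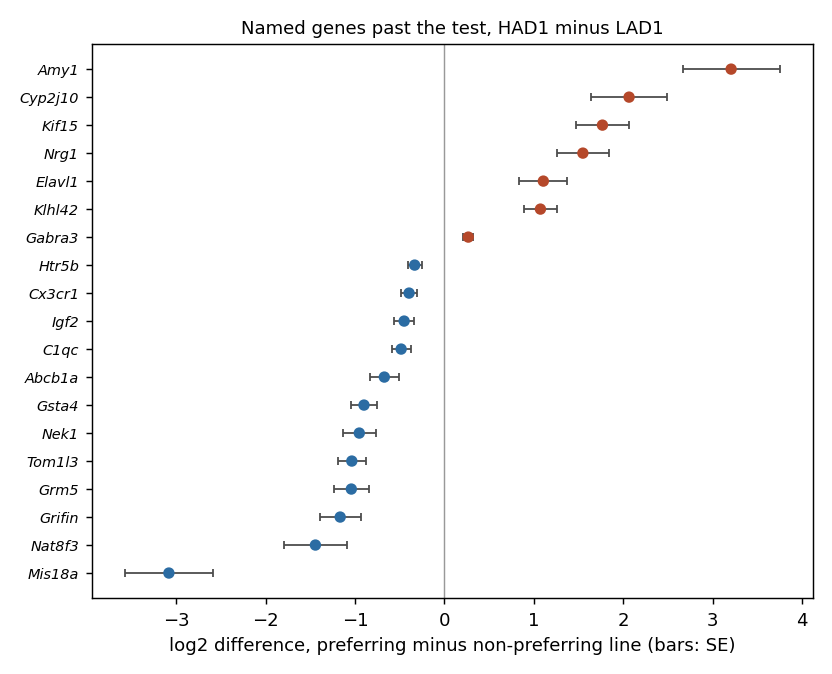
Log2 difference (horizontal axis, HAD1 minus LAD1) of the named genes past the test, 9 HAD1 and 10 LAD1 arrays as labelled; points are differences and bars standard errors. Amy1 was 3.21 higher and Mis18a fell by 3.08.

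In P and NP, AA and ANA, and sP and sNP rats no probe set passed the limma test over all 31042 as labelled. The counts at an unadjusted p under 0.05 were 1523, 1528 and 1341 probe sets. The genes with the smallest p, chosen after their values were seen, were Mtarc2, Eri2, Mak and Clec4a3 for P and NP, of which Mtarc2, a mitochondrial reductase, was closest at -0.39 (SE 0.06, adjusted p = 0.0601). Mtarc2 in P/NP passed with 1 probe set per gene (adjusted p = 0.0236), in the brighter 50% (adjusted p = 0.0326) and with array weights, where 3 probe sets passed; its adjusted p ranged from 0.0011 to 0.4156 over the alternatives. For AA and ANA they were Rexo4 at -0.65, Wdr37 at -1.41, Capn1 at 0.31 and Nepn at -0.66 (adjusted p = 0.5016 each), with another probe set of Wdr37 at -0.04 (adjusted p = 0.9832), and for sP and sNP E4f1 at 0.18 (adjusted p = 0.3587), Bin2a at -0.20, Pnpla1 at 0.25 and Nkg7 at -0.15. With all 10 groups in 1 fit, which pools the spread, the counts were 168, 203 and 2, and array weights gave 207 for AA and ANA. Single arrays decided small counts: P and NP had 5 without P 1, 1 without P 2, 6 without P 9 and 25 without NP 9, and AA and ANA had 10 without ANA 16. Without the doubted arrays the counts were 502 (288 higher, 214 lower) for P and NP, 559 (256 and 303) for AA and ANA, and 542 (272 and 270) for sP and sNP. Of the genes named for these pairs, Mtarc2, Eri2, Clec4a3, Rexo4, Wdr37, Nepn, E4f1 and Pnpla1 then passed, Wdr37 at -2.10, and Mak, Capn1, Bin2a and Nkg7 did not. With arrays chosen on 1 set of chromosomes and probe sets tested on the other, 244, 330 and 293 of 20136 probe sets passed, against 1, 0 and 0 as labelled. Nearly the same arrays were left out here as by the doubted list.

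Among genes fixed beforehand for their part in alcohol preference, 4 were measured and none was called in any pair with all arrays. Npy, a neuropeptide, differed by -0.10 (SE 0.12) in HAD1, 0.04 (SE 0.12) in HAD2, -0.06 (SE 0.24) in P, -0.10 (SE 0.17) in AA and 0.19 (SE 0.15) in sP. Grm2, a presynaptic glutamate receptor, ranged from -0.19 in HAD1 to 0.45 in sP (SE 0.28); without the doubted arrays it was 0.96 in sP and passed (adjusted p = 0.0334). Crh, the corticotropin-releasing hormone, ranged from -0.50 in HAD2 (SE 0.38) to 0.67 in HAD1 (SE 0.24). Gabra2, a GABA receptor subunit, was positive in 5 of 5 pairs, from 0.14 to 0.29 (-0.03 in HAD1 when LAD1 36 is counted as HAD1), with a mean of 0.21 (SE 0.06, adjusted p = 0.0965). This mean was 0.27 without the doubted arrays and passed (adjusted p = 0.0112).

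In the 3 pairs without calls no list had members past the test with all arrays. Camera called 3 lists in P rats: choroid plexus markers (10 of 10 positive, median 0.41, adjusted p = 0.0484), and, with negative medians, microglial (adjusted p = 0.0237) and vascular markers (adjusted p = 0.0484). With an estimated correlation adjusted p = 0.967 for each. It called 6 in AA rats, among them glucocorticoid response (median -0.14, adjusted p = 2.26e-04) and striatal markers (median -0.23, adjusted p = 5.47e-04). With an estimated correlation these had adjusted p = 0.324 and adjusted p = 0.811. The other AA lists were glutathione, respiratory chain and oligodendrocyte genes, with negative medians, and vascular markers, with a positive median. For these an estimated correlation gave adjusted p = 0.811 for glutathione genes and adjusted p = 0.870 for the rest. It called 6 in sP rats, among them vascular (median 0.12, adjusted p = 1.42e-05) and striatal markers (median 0.28, adjusted p = 9.66e-05). With an estimated correlation these had adjusted p = 0.329 and adjusted p = 0.357. The other sP lists were glutamate, cAMP signalling and alcohol preference candidate genes, with positive medians, and glucocorticoid response, with a negative median. For these an estimated correlation gave adjusted p = 0.184, adjusted p = 0.169, adjusted p = 0.271 and adjusted p = 0.329 in that order. List members passed in all 3 pairs without the doubted arrays, among them 2 microglial markers lower in P, 2 glutathione genes lower in AA and 3 vascular markers higher in sP. Camera then no longer called choroid plexus (adjusted p = 0.1517) or vascular markers (adjusted p = 0.1528) in P, called microglial markers lower at adjusted p = 6.60e-05, and newly called glutathione genes higher (adjusted p = 0.0279). In AA it no longer called respiratory chain genes (adjusted p = 0.2365) or vascular markers (adjusted p = 0.2586). In sP it newly called immediate early genes (adjusted p = 0.0400) and microglial markers (adjusted p = 0.0099), both higher. With an estimated correlation 0 lists passed in any contrast, with all arrays or without the doubted ones; for the newly called lists adjusted p = 0.8526 in P, and adjusted p = 0.8421 and adjusted p = 0.6736 in sP.

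On average over the 5 pairs, with 47 arrays of preferring and 49 of the other lines, 306 probe sets passed, 146 higher and 160 lower in preferring lines. This test and its standard errors take animals as replicates. With the line pair as replicate, the unit in which selection was repeated, 0 probe sets passed. RT1-T24-4 was 0.90 higher (SE 0.17), Kif15 0.76 (SE 0.10), Vof16 0.68 (SE 0.15), Jhy 0.57 (SE 0.12) and RT1-CE16 0.48 (SE 0.11). Vof16, Jhy and RT1-CE16 were positive in 5 of 5 pairs, Kif15 in 4 and RT1-T24-4 in 3. Gpatch11, Ncaph, Rorb, Ypel1 and Adcy9 were higher by 0.27 to 0.34, while another probe set of Ypel1 gave -0.06. Other probe sets of Vof16 (0.30), Gpatch11 (0.12), Rorb (0.07), Grm5 (-0.05), Elavl1 (-0.02 and -0.16) and RT1-A3 (-0.01) had the sign of the first, and none of these, nor that of Ypel1, passed. Adcy9 was positive in 5 pairs, Ncaph, Rorb and Ypel1 in 4 and Gpatch11 in 3. Mis18a fell by 0.70 (SE 0.12), RT1-T24-3 by 0.67 (SE 0.16), Grm5 by 0.65 (SE 0.10), Aldh1a1 by 0.53 (SE 0.10), Pnlip by 0.46 (SE 0.06) and Fcgr2b, an Fc receptor of immune cells, by 0.41 (SE 0.09). Nek1, Tom1l3, Elavl1 and Rexo4 fell by 0.33 to 0.40, RT1-A3 by 0.16 and Cx3cr1 by 0.16. RT1-T24-3, Fcgr2b and RT1-A3 were negative in 5 pairs, Aldh1a1, Pnlip, Tom1l3 and Cx3cr1 in 4, and Mis18a, Grm5, Nek1, Elavl1 and Rexo4 in 3. Such tallies count signs near 0 as well. Mis18a was at -3.08 in HAD1, -0.39 in HAD2 and between -0.02 and 0.01 in the other pairs. Pnlip was at -2.11 in HAD2 and between -0.13 and 0.08 elsewhere, and Rorb at 1.02 in HAD2 and between -0.01 and 0.20 elsewhere. Ypel1 was at 0.90 in HAD2, 0.42 in HAD1 and between -0.05 and 0.04 elsewhere. The mean of Elavl1 was -0.25 without the doubted arrays and no longer passed (adjusted p = 0.0982). Camera called microglial markers (2 of 13 positive, 1 past the test, 4 adjusted over the list alone, adjusted p = 6.89e-07) and glucocorticoid response (0 of 15 positive, adjusted p = 0.0330); with an estimated correlation adjusted p = 0.400 and adjusted p = 0.584. It also called vascular markers higher without the doubted arrays (adjusted p = 0.0062), with adjusted p = 0.8285 with an estimated correlation. The first 2 lists did not move alike in all pairs. Positive microglial markers numbered 0 of 13 in HAD1, 3 in HAD2, 4 in P, 6 in AA and 10 in sP. Positive glucocorticoid genes numbered 3 of 15 in HAD1, 10 in HAD2, 7 in P, 1 in AA and 3 in sP. Without the arrays of HAD2 and LAD2 73 probe sets passed, with 1 probe set per gene 108, and without the doubted arrays 901.

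Many differences varied among pairs, by a test that gave 67 false calls beside 197 recovered changes in simulated data. The F test found 1409 such probe sets (409 without the arrays of HAD2 and LAD2, 543 with 1 probe set per gene, 3265 without the doubted arrays), led by Irgq, Pnlip, Gpatch11, Elavl1 and Sgcb. Elavl1 was 1.11 higher in HAD1 and fell by 1.96 in HAD2. With the line pair as replicate 0 probe sets passed in limma (1039 at an unadjusted p under 0.05, smallest adjusted p = 0.322). As labelled, 0 probe sets changed the same way in at least 3 pairs, with 0 expected because 3 pairs had no calls. Without the doubted arrays there were 41 (0.902 expected), with 4 in at least 4 pairs (0.0049 expected) and 1 in all 5 (1.02e-05 expected). These expected numbers take every probe set as equally likely to be called. Between the 2 HAD pairs the opposite direction exceeded such a number as well, so the excess does not by itself show sharing through preference. HAD1 with LAD1 and HAD2 with LAD2, replicate selections by their names, shared 100 called probe sets. Of these 50 had the same direction (6.12 expected from independent lists) and 50 the opposite direction (6.13 expected). Both pairs shared 242 without the doubted arrays, 135 in the same direction (16.3 expected) and 107 in the opposite direction (16.3 expected). Amy1, Kif15, Grm5, Nek1, Tom1l3, Gsta4 and Cx3cr1 were called in the same direction in both, and Elavl1, Klhl42, Grifin and Abcb1a in opposite directions. Across probe sets the 10 correlations of differences between pairs ranged from -0.13 to 0.08, none past a permutation test (smallest permutation p = 0.238, 0.990 after adjustment).

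**Figure D4:**
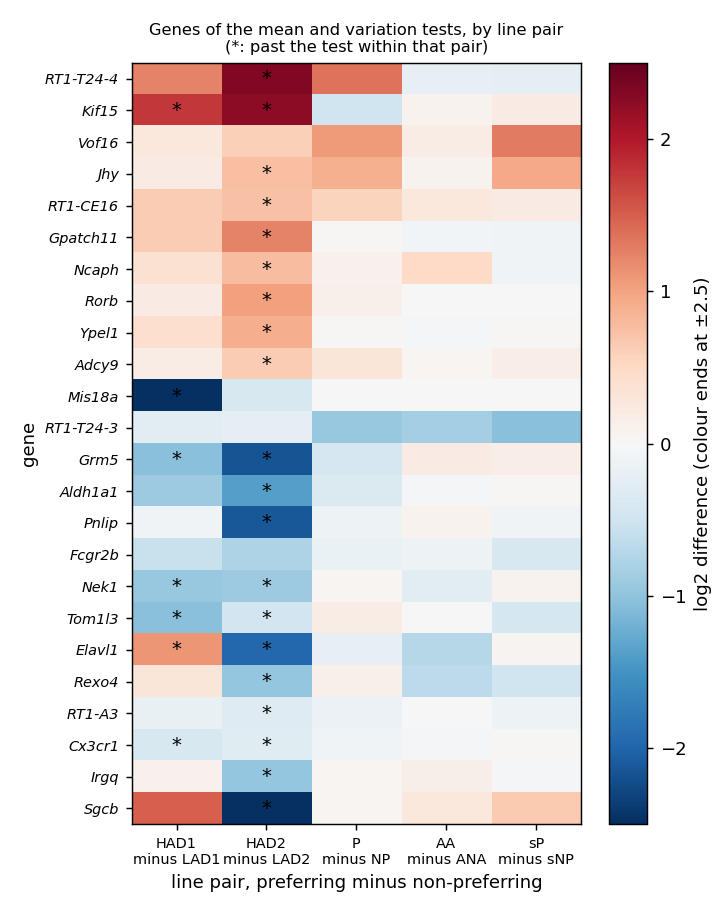
Log2 differences (colour, preferring minus non-preferring line) of the genes of the mean and variation tests in the 5 line pairs; stars mark differences past the test within that pair. Stars occur only in the HAD1 and HAD2 columns, and Elavl1 is 1.11 higher in HAD1 and 1.96 lower in HAD2.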

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

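The tests of array positions on single chromosomes and of the ratio of 3' to 5' control probe sets were chosen only after the results they measure had been seen, and the intervals of the ratios for markers and controls were added after those ratios.

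Single arrays stood apart from their group in 34 of 176 sets of values, at a cut passed by chance in about 5% of sets. These sets are not independent, as many are genes named for large line differences, measured on the same arrays. An array near the other line stands apart in such genes by construction. Of the 28 outliers among gene values, 16 lay in doubted arrays. The numbers in brackets below are the gap to the nearest array divided by the group's range. HAD1 28 stood apart in its position (0.83) and in Amy1 (0.67), Cyp2j10 (0.67), Kif15 (0.56), Nrg1 (0.66), Klhl42 (0.83), Mis18a (0.83), Nat8f3 (0.72) and Grifin (0.78). LAD1 37 did so in its position (0.69) and in Amy1 (0.88), Cyp2j10 (0.60), Kif15 (0.62), Elavl1 (0.54), Klhl42 (0.50) and Mis18a (0.85). ANA 16 stood apart in position (0.49), Rexo4 (0.72) and Wdr37 (0.61). Among other arrays, HAD1 25 stood apart in Gabra3 (0.49), HAD1 22 in Grm5 (0.61), HAD2 6 in Kif15 (0.59), Tstd1 (0.48), RT1-S3 (0.51) and Crh (0.70), and LAD2 20 in position (0.49) and Fcrl2 (0.52). LAD2 14 stood apart in RT1-S3 (0.56), LAD2 17 in Adcy9 (0.50), LAD2 11 in Siglec5 (0.51), ANA 14 in Npy (0.63) and P 5 in Mak (0.48). NP 10 (0.63) and AA 17 (0.68) stood apart in the ratio of 3' to 5' control probe sets. By the F test 1409 probe sets, and 33 of the 50 named genes past a test, differed between line pairs in their difference; the named genes were chosen for large differences in a pair or the mean, or for a small p of this test, so their share is raised by the choice.

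Arrays on the other line's side occurred in 4 line pairs, with out-of-place arrays in both lines of each. Haplotypes segregating within a line would put an array on the other side on some chromosomes only. Arrays doubted on odd chromosomes lay on the other side on a median share of 1 of the even chromosomes, each scored alone; 14 of these 16 arrays reached at least 0.8, and 0 of the 80 other arrays did, which argues against segregation. Marker lists of doubted arrays deviated from the labelled group 0.960 times as much as those of the other arrays (95% interval 0.792 to 1.18). This argues against a larger shift in cell composition across the lists as a whole. The value averages over 9 lists, so a shift in 1 cell type could be missed and stays open. Mislabelled arrays may account for the 14, found and tested on the same data. Among these 14, NP 1 lay near the midpoint at 0.49 and 0.22, short of the median of P. The array sP 2, also among them, was nearly the same as sNP 2. RNA quality cannot be told apart, with a ratio of control deviations of 1.05 and an interval of 0.275 to 3.46. ANA 18 and ANA 20, at a share of 0.3, lie below what a wrong label needs, and segregation stays open for them because other arrays also reached 0.3; mixed RNA was not tested.

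The pair sP 2 and sNP 2 could come from 1 RNA hybridised to both arrays. Their control probe sets, which had no part in finding the pattern but include actin and GAPDH, also differed least among the 136 array pairs of sP and sNP, a rank share of 0.0074. A copied or shared hybridisation would give the same, so the step at which they became alike is open, and no biological explanation was tested.

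Other splits of the same arrays into groups of the same sizes tested whether an arbitrary division of the arrays gives such counts. For HAD2 and LAD2, 1 of 100 splits, the real one, reached 1271, with 1225 the highest of the others. For HAD1 and LAD1, 2 of 100 reached 299, the other of them giving 1789. For the mean over pairs 2 of 100 reached 306 (highest other 590), and for variation 1 of 100 reached 1409 (highest other 1035). Under a share of 0.05 of the splits reached these 4 counts, so an arbitrary division of the arrays seldom gives them. The splits exchange animals within pairs and cannot test chance differences between lines, for which the line pair is the unit. The counts of 0 in P and NP, AA and ANA, and sP and sNP were reached by 100 of 100 splits, which any split does and which therefore tests nothing; other splits gave up to 1836, 31 and 96. The split giving 1789 for HAD1 and LAD1 called several times the real count. For P and NP, the split giving 1836 called many probe sets where the labels called 0. Which arrays these splits put together was not examined, so what sets those arrays apart is open. With the line pair as replicate 16 of 16 splits reached 0 and the highest other was 0; this tests nothing either, and 16 splits are too few for a share under 0.05. List counts were not told from chance: 67 of 100 splits gave at least 2 lists for HAD1 and LAD1 (highest other 17), 87 at least 1 for HAD2 and LAD2 (highest other 13) and 78 at least 2 for the mean (highest other 16).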

How the results depend on the processing

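The alternatives without doubted, hand-picked or nearly identical arrays were chosen only after the data had been seen. Counts for HAD2 and LAD2 stayed within 1.5 times of 1271 with a 1.2-fold minimum, no intensity trend, quantile normalization, array weights, the 3' to 5' covariate and all groups in 1 fit, from 1012 to 1815. No detection calls were used, so signal near background limits what low probe sets show.

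Counts were lower with fewer probe sets tested for HAD1 and LAD1, HAD2 and LAD2, the mean and variation. A smaller number tested lowers counts by itself. AA and ANA and sP and sNP stayed at 0, and P and NP rose to 1. In the brighter 50% the counts were 182 for HAD1 and LAD1, 831 for HAD2 and LAD2, 1 for P and NP, 188 for the mean and 891 for variation. With 1 probe set per gene they were 78, 526, 1, 108 and 543 in that order. That setting tested 14217 of the 31042 probe sets. Apart from P and NP, the counts fell by more than that proportion, most for HAD1 and LAD1, from 299 to 78. Why they did was not tested. The crossed chromosomes gave 690 for HAD2 and LAD2, as did the labels over the same 20136 probe sets, with 0 arrays left out. Array weights gave 700 for HAD1 and LAD1, 3 for P and NP, 207 for AA and ANA, 692 for the mean and 3972 for variation. All 10 groups in 1 fit gave 785, 168 and 203 for HAD1, P and AA with their partners, and 2 for sP and sNP. The mean fell to 109 with a 1.2-fold minimum and 186 in an additive model. LAD1 36 counted as HAD1 left 4. The cause was not tested for weights, the single fit, the fold minimum, the additive model and LAD1 36.

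Without the doubted arrays the counts were 796 for HAD1 and LAD1, 502 for P and NP, 559 for AA and ANA, 542 for sP and sNP, 901 for the mean, 3265 for variation and 41 changed the same way in at least 3 pairs. Without the hand-picked arrays they were 796, 502, 579 and 528 for these pairs, 898 for the mean and 3343 for variation. Crossed chromosomes gave 244 for P and NP, 330 for AA and ANA and 293 for sP and sNP. With the line pair as replicate the count was 0 in limma under every alternative run. Without sP 2 and sNP 2 the count for sP and sNP was 0, for the mean 295 and for variation 1430. Blocking by replicate number gave 0 for P and NP and 0 for sP and sNP; arrays sharing a number had median correlations of 0.11 and 0.09, and the numbers do not pair them.

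Leaving out single arrays gave 157 to 600 for HAD1 and LAD1, 1082 to 1730 for HAD2 and LAD2, 0 to 25 for P and NP, 0 to 10 for AA and ANA and 0 for sP and sNP. Leaving out line pairs gave 73 to 446 for the mean and 409 to 1347 for variation, both lowest without HAD2 and LAD2. List counts by camera with an estimated correlation were 0 in every contrast, and by fry with all arrays 1 for HAD1 and LAD1 and 0 elsewhere. Without the doubted arrays fry gave 1 for HAD1 and LAD1, 2 for sP and sNP (vascular markers, adjusted p = 0.0137, and glucocorticoid response, adjusted p = 0.0158), 2 for the mean (microglial markers and glucocorticoid response, adjusted p = 0.0347 each) and 0 elsewhere.

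Correlations near 0 changed sign. In the brighter 50% HAD1/LAD1 gave 0.0027 with P/NP and 0.0130 with sP/sNP. As Spearman's rho HAD1/LAD1 gave 0.0448 with P/NP and 0.0238 with sP/sNP, HAD2/LAD2 gave 0.0060 with P/NP, and AA/ANA gave -0.0510 with sP/sNP. Without the doubted arrays HAD1/LAD1 gave 0.0039 with HAD2/LAD2 and AA/ANA gave -0.0308 with sP/sNP. Other probe sets had the opposite sign for Nrg1 (-0.0087), Elavl1 (-0.1146), Grm5 (0.0528) and Igf2 (0.0427, 0.0413 and 0.0828) in HAD1/LAD1, for Sgcb (0.3114 and 0.5894) and Elavl1 (0.1172) in HAD2/LAD2, for Ypel1 in the mean (-0.0564) and for Eri2 in P/NP (0.0586). Among genes past no test, Gabra2 in HAD1/LAD1 was -0.0253 with LAD1 36 as HAD1, and Grm2 in AA/ANA was -0.3668 with array weights and -0.2057 without the doubted arrays. Crh in sP/sNP was 0.1608 with array weights and 0.0020 with the 3' to 5' covariate, Npy in the mean 0.0196 and 0.0022 under the same settings, and Grm2 in the mean -0.0081 with array weights. The cause was not tested. In all, 784 values of named genes under alternatives kept their direction and side of the threshold, 71 no longer passed, 24 newly passed and 19 changed sign. Most of these values refit the same probe set and include genes past no test. Other probe sets of named genes, which measure a gene anew, kept direction and side of the threshold in 8 cases. In 21 cases they had the same sign without passing, and in 11 the opposite sign.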

Other observations

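The exchange of labels was chosen only after the array positions had been seen; the tests of other probe sets and of neighbouring genes were set beforehand.

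Called genes of HAD2 and LAD2 lay next to each other more often than shuffled calls would. Among 14163 measured genes in chromosome order, 42 neighbouring pairs were both called against 19.9 expected, a ratio of 2.109 (permutation p = 2.00e-04, 10000 permutations). For HAD1 and LAD1 there were 3 against 0.653 expected (permutation p = 0.0290). In 17 of the 42 both genes changed in the same direction. This is consistent with blocks of linked genes inherited together in each line; this is a hypothesis, and shared regulation of neighbours was not tested. Sequence variants under the probes are another candidate explanation and stay open: 159 of 247 other probe sets of called genes, a share of 0.644, had the sign of the called one, and 51 were called themselves, 36 of them with the same sign. For HAD1 and LAD1 it was 31 of 49, a share of 0.633. Among other probe sets in the brighter 50% of the array the shares were 0.615 for HAD2 and LAD2 and 0.429 for HAD1 and LAD1, the latter from 14 probe sets.

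Wrong labels can empty a comparison of this kind. When the labels of 2 HAD2 and 2 LAD2 arrays were exchanged on purpose, the count fell from 1271 to 4 probe sets, and the position score found 4 of the 4 exchanged arrays and 0 others.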
